A study of Homo sapiens with 36 samples.

How the data were processed

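RNA-seq was done on U2OS cells stably expressing GR alpha, kept in low-glucose medium with serum. Cells were transfected with siRNA using a lipid reagent and 48 h later were given 100 nM dex or ethanol for 8 h. Total RNA was then extracted with TRIzol and sequenced from standard Illumina libraries. Per the labels there are 6 siRNA conditions with 3 biological replicates each, on different days, which gives 36 libraries in 12 groups. The study's own question, per its description, is whether genes whose regulation Hic-5 blocks need the remodelers CHD9 and BRM when Hic-5 is absent.

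The authors mapped reads with TopHat2 2.1.1 to the GRCh38 build and normalised with edgeR, per the submitters' processing notes. The read counter, the annotation and the edgeR version are not given in the sources used here. The deposited table gives 15186 genes by 36 libraries. Its name speaks of upper-quartile normalised CPM, but the deposited values are raw counts: all are whole numbers, and their totals run from 27.4 to 47.1 M per library (lowest over highest 0.582), with upper quartiles of 1731.75 to 2973. The values were therefore treated as counts. Gene identifiers are Entrez IDs with symbols; 30 genes carry no symbol in the file, of which 1 was named from the RefSeq table, and 15116 genes (99.5%) matched the RefSeq table by Entrez ID. No column belonged to another series (0).

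The test written down before the data were examined was limma on log2(CPM + 0.5). Since the table holds counts, edgeR 4.0.16 quasi-likelihood fits (glmQLFit and glmQLFTest, with upper-quartile factors from calcNormFactors) in R 4.3.3 became the test, and the planned test was kept as an alternative. All 36 libraries were fitted together with 12 group means, so that the groups share 24 residual degrees of freedom. Genes with an upper-quartile scaled CPM above 1 in at least 3 libraries were tested, 15179 in all, which left out 7. The p values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, and a gene was called at an adjusted p under 0.05. The 16 comparisons were the 6 dex responses, 5 differences of dex responses (interaction contrasts) and 5 comparisons of an siRNA condition with siNSsiNS among vehicle libraries. CPM values in the text were scaled by the same factors, and a count of 3 or fewer over the libraries of a group (11 named genes) led to no fold being given there, a rule set after the counts were seen.

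Whether the replicate numbers pair libraries was checked from residual correlations. The 18 vehicle and dex pairs of one condition and number gave correlations of 0.458 to 0.922, and 100% of libraries were closest to the library of their own number. Across siRNA conditions every pair passed 0.1 in only 2 of 5 comparisons (range -0.213 to 0.722). A second fit with a term for each of the 18 pairs and 6 dex terms (12 residual degrees of freedom) is therefore printed beside the first wherever dex responses are given; it was chosen after the pairing was seen. The median biological coefficient of variation was 19.0% without and 7.59% with this block. Pairs of libraries were checked for copies, and the lowest chi-square per degree of freedom over 36 pairs was 9.41, on genes with a count of at least 20.

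Each fit was tested on its own simulated data, with the design of these libraries, 15179 genes and the means and dispersions of that fit. The data for the fit without the block held no pair effects. The shares with and without the block are therefore not from the same data. For a dex response, genes changed 1.5-, 2- and 4-fold were recovered in 26.9%, 70.1% and 92.4% of cases without the block (4 false calls) and in 76.1%, 88.1% and 97.0% with it (9 false calls). For a difference of dex responses the shares were 8.96%, 40.3% and 77.3% without (6 false calls) and 62.7%, 80.6% and 93.9% with the block (8 false calls). Of the simulated lists, 1 of 1 changed and 0 of 20 unchanged were called in each fit. Genes were drawn independently, so these lists cannot test camera where genes are correlated.

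The 21 gene lists were written from general knowledge before the data were examined. Their members among tested genes were tested with camera of limma 3.58.1, with its preset correlation of 0.01 and again with the correlation estimated from the residuals, and adjusted over the lists of a comparison. Members called are counted at the adjusted p over all genes and, where said, adjusted over the list alone. Genes named in the report follow a rule fixed before the data were examined. It names the 4 genes of the siRNA targets and GR, the called genes with a mean CPM of at least 1, non-overlapping groups and the largest changes (10 each way for dex with siNSsiNS and siHic5siNS, 6 each way elsewhere), up to 4 called members of each list with the smallest p, and the block genes with the largest rises (12) and falls (8). Where a dex fall or a difference was called only with the replicate block, the same rule was applied to that fit, which was decided after the pairing was seen. The rule gives 321 genes; antisense, clone and other unnamed transcripts were counted but not named. The result of 1 gene that the rule gives is not reported here. CDH20, GREB1, MUM1L1, PTPN1, ADM, PKP2, RNA28S5 and those of the genes raised in all 6 conditions that the rule does not give were chosen after their values were seen.

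Block genes were defined as in the report. For their held-out response, genes were chosen on 2 replicate numbers and their median log2 change, signed by direction, was taken in the left-out number. The 3 differences from siHic5siNS, paired by left-out number because each number has its own genes, were tested by exact permutation of their signs, the smallest two-sided p of which is 0.25. This took the place of a first comparison over all 20 splits of 6 values, which ignored the pairs; the change was made after the result was seen. Vehicle changes were correlated across genes only between comparisons without a common library.

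Alternatives were set down before the data were examined (other filters, pseudocounts, limma without trend or robust steps, quantile normalization, median-ratio scaling, DESeq2 1.42.0, the replicate number as a block over all groups, a fold of 1.5 or more, only the compared groups in the fit, and each library or replicate number left out) or added after (the block within siRNA condition, TMM scaling, limma with a pseudocount of 0.5 in place of its planned part as the test, and a fit without the 6 siBRMsiNS libraries). Length and GC offsets were fitted with natural splines of 5 degrees of freedom on GENCODE 29 transcripts, which gave a length to 97.7% of genes. Group labels were exchanged in all possible ways within a comparison to see how large counts become without the real grouping. The random seed was 1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Reads, splice forms and protein levels were not analysed here.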

Results

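The 36 libraries came from U2OS osteosarcoma cells that stably carry the glucocorticoid receptor alpha (GR). They form 12 groups of 3: 6 siRNA conditions, each with 8 h of 100 nM dexamethasone (dex) or of ethanol vehicle, starting 48 h after transfection. The conditions were a non-silencing control (siNSsiNS), siRNA labelled as against Hic-5 (siHic5siNS), CHD9 (siCHD9siNS) or BRM (siBRMsiNS), and the paired siRNAs siCHD9siHic5 and siBRMsiHic5. The labels state that the 3 biological replicates of each condition were made on different days. Library totals lay between 27.4 and 47.1 M counts. In all 15179 genes were tested. Changes are log2 fold changes with their standard errors from edgeR, and levels are upper-quartile scaled CPM with the SD over the 3 libraries of a group. Vehicle and dex libraries with the same number within a condition proved to be paired, so each dex count is also given with a replicate block within the siRNA condition. The fit without the block leaves this pairing out. Its counts of 0 and high adjusted p values for dex responses and their differences are therefore no evidence of absence. The counts given at an unadjusted p under 0.05 all lie under a share of 0.05 of the tested genes. In the fit without the block that share is no measure of chance, since the pairing is left out. Those counts are therefore evidence neither of an effect nor of its absence.

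The first question was whether the transcripts of the siRNA targets fell. TGFB1I1, which encodes the LIM-domain coregulator Hic-5, stood at 28.4 ± 0.785 CPM in the siNSsiNS vehicle libraries and at 7.07 ± 3.58 CPM with siHic5siNS, which is 24.8% of the control level (adjusted p = 1.45e-07). It stood at 26.2% with siCHD9siHic5 (adjusted p = 2.04e-07) and at 18.3% with siBRMsiHic5 (adjusted p = 4.71e-08). SMARCA2, the gene of the SWI/SNF ATPase BRM, fell from 30.3 ± 4.74 to 8.76 ± 1.18 CPM with siBRMsiNS (28.9%, adjusted p = 1.01e-06) and to 7.56 ± 1.53 CPM with siBRMsiHic5 (24.9%, adjusted p = 1.04e-08). CHD9, a chromodomain helicase, was at 67.9% of the control level in the vehicle libraries labelled siCHD9siNS (60.1 ± 8.94 against 88.6 ± 9.46 CPM, adjusted p = 0.0192). With dex it was at 85.5% (adjusted p = 0.411). The libraries labelled siCHD9siHic5 had the highest mean CHD9 level: 123 ± 17.9 CPM with vehicle, 1.81-fold the level with siHic5siNS (adjusted p = 0.00033) and 1.39-fold the level with siNSsiNS (adjusted p = 0.0291). With dex it stood at 1.85-fold the level with siHic5siNS (adjusted p = 0.000227), where CHD9 was itself at 71.3% of control (adjusted p = 0.0244). Against siNSsiNS with dex it was 1.32-fold and not called (adjusted p = 0.0668). CHD9 was also lower with siBRMsiHic5, at 45.2 ± 5.50 CPM (51.1% of control, adjusted p = 0.000105). NR3C1, the gene of GR, rose 1.48-fold with siHic5siNS (adjusted p = 0.0026) and 1.28-fold with siCHD9siHic5 (adjusted p = 0.0498) in vehicle libraries, and was not called with the other 3 conditions. Since the CHD9 transcript runs against the label in siCHD9siHic5, groups are named below by their labels, and no effect is assigned to loss of CHD9. The call of CHD9 against siNSsiNS with vehicle was lost without some single libraries for siCHD9siNS and siCHD9siHic5, with the direction kept, and was kept without any 1 library for siBRMsiHic5. For siRNA targets: CHD9 with siCHD9siNS, vehicle, the log2 change of -0.56 became -0.49 without siNSsiNS replicate 1 (adjusted p = 0.0775), -0.55 without siCHD9siNS replicate 1 (adjusted p = 0.0601) and -0.46 without siCHD9siNS replicate 2 (adjusted p = 0.0849). For siRNA targets: CHD9 with siCHD9siHic5, vehicle, the 0.47 became 0.35 without siCHD9siHic5 replicate 1 (adjusted p = 0.151), 0.39 without siNSsiNS replicate 2 (adjusted p = 0.119) and 0.50 without siNSsiNS replicate 3 (adjusted p = 0.0502). The call against siHic5siNS was kept in each case, at a log2 change of 0.73 to 0.96.

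**Figure D1:**
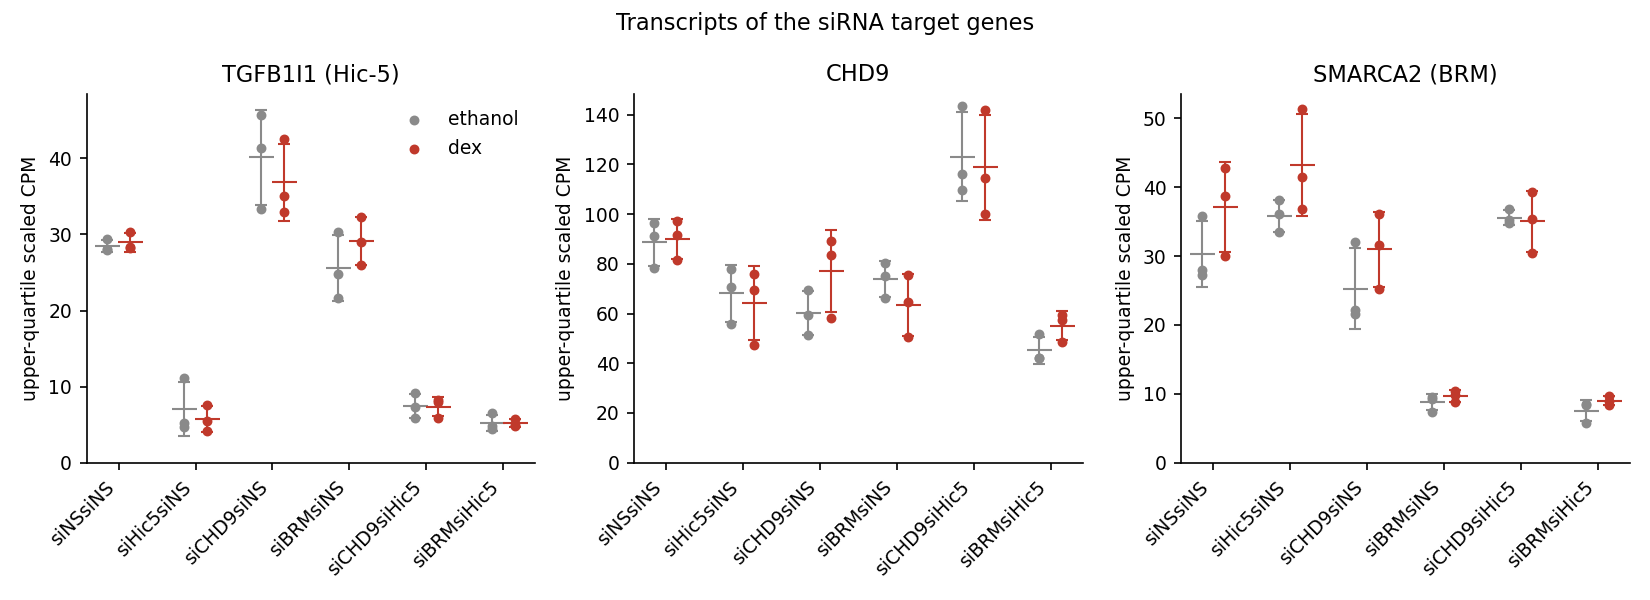
Upper-quartile scaled CPM of TGFB1I1, CHD9 and SMARCA2 in the 12 groups, with ethanol in grey and dex in red. Points are single libraries, horizontal marks are means and bars are SD (n = 3); CHD9 averages 123 CPM in the vehicle libraries labelled siCHD9siHic5 and 88.6 CPM in the control libraries.

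In cells with control siRNA, the question was which genes answered dex. SPINK13, a serine peptidase inhibitor, rose by 4.31 ± 0.50 on the log2 scale (adjusted p = 2.91e-05), and EDN3, the vasoactive peptide endothelin 3, rose by 3.06 ± 0.64 (adjusted p = 0.0213). CACNA1I, a T-type calcium channel subunit, rose by 2.58 ± 0.37 and KCNA4, a voltage-gated potassium channel, by 2.43 ± 0.35 (both adjusted p = 0.000356). FAM107A (2.77 ± 0.57), the transcription factor KLF15 (2.37 ± 0.39), DNER (2.34 ± 0.37), CLVS2 (1.98 ± 0.34) and the synaptic vesicle glycoprotein SV2B (1.91 ± 0.41) rose as well. Among 33 tested genes that glucocorticoids are known to induce, 10 rose and 0 fell (16 rose when adjusted over the list alone). They included TSC22D3, which encodes the GR-induced leucine zipper protein GILZ (1.63 ± 0.25), the ADP-ribosyltransferase TIPARP (1.59 ± 0.24), SCNN1A, the alpha subunit of the epithelial sodium channel (1.57 ± 0.25), and the GR co-chaperone FKBP5 (1.48 ± 0.28). The list rose as a set (camera adjusted p = 5.05e-63, and adjusted p = 1.39e-06 with an estimated correlation). Of the 4 metallothioneins tested, MT1X (1.01 ± 0.22), MT2A (0.87 ± 0.19) and MT1E (1.14 ± 0.26) rose, but reads of these close paralogs were not told apart here. Of 13 adipocyte differentiation genes, KLF15 and ZBTB16 (1.61 ± 0.30) rose. The set rose (adjusted p = 6.92e-08). Its members KLF15, ZBTB16, CEBPB, CEBPD and ANGPTL4 are also on the glucocorticoid-induced list. So are MT1X and MT2A, SCNN1A and SGK1 of the ion channel and transporter list, and FKBP5 of the steroid receptor list. These lists are therefore not separate results, here or in the other conditions.

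Of 17 inflammatory genes that glucocorticoids are known to repress and of 16 immediate early genes, 0 and 0 passed the test singly with siNSsiNS, also when adjusted over the list alone. As sets, the inflammatory genes fell (adjusted p = 4.44e-06, but adjusted p = 0.243 with an estimated correlation), as did the immediate early genes (adjusted p = 4.72e-07, and adjusted p = 0.248 with an estimated correlation) and the 23 TGF-beta targets (adjusted p = 0.000121, and adjusted p = 0.243 with an estimated correlation). The 8 ion channel and transporter genes raised by corticosteroids, of which SCNN1A was called, rose as a set (adjusted p = 0.00701, and adjusted p = 0.139 with an estimated correlation). In all, 52 genes rose and 0 fell at an adjusted p under 0.05 in edgeR (379 genes at an unadjusted p under 0.05). The control and dex libraries of all 52 did not overlap, but these genes were called on those same libraries. Over all genes the share without overlap was 8.16%. By chance it would be 10% for unpaired libraries. Pairing makes such separation rarer, so the 10% is too high a reference for this and the other dex responses. With the replicate block, 272 genes rose and 91 fell. The falls called only with the block included VEGFA, the angiogenic growth factor (-0.50 ± 0.10, adjusted p = 0.013 against 1.00 without the block), the calcium-activated potassium channel KCNN4 (-0.44 ± 0.07, adjusted p = 0.000515 against 1.00) and PODXL, a sialomucin (-0.51 ± 0.09, adjusted p = 0.00249 against 1.00). With TMM factors the blocked split was 244 up and 116 down, and with no factors 365 up and 61 down. The count for the dex response with siNSsiNS was 23, 28 and 25 without vehicle replicate 1, 2 or 3 and 25 and 29 without dex replicate 1 or 3. With the block, 143 genes were called without pair 1.

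With Hic-5 depleted, SPINK13 rose by 6.61 ± 0.57 (adjusted p = 4.56e-08). Large rises were also seen for SHOX, a homeobox factor (4.68 ± 0.79), RASGRP2, an exchange factor for Rap1 (3.82 ± 0.51), SLC38A4, an amino acid transporter (3.81 ± 0.48), and CDH15, the muscle cadherin (3.71 ± 0.60). CACNA1I (3.59 ± 0.39), the adhesion receptor ADGRF4 (3.12 ± 0.36) and FAM107A (3.06 ± 0.57) rose as well. Genes that fell were led by RGS16, a regulator of G protein signalling (-1.69 ± 0.35, adjusted p = 0.00994), TNFRSF11B, which encodes the RANKL decoy receptor osteoprotegerin (-1.45 ± 0.35), the cytokine LIF (-1.29 ± 0.25), the transcription factor ZBTB20 (-1.28 ± 0.25) and the signalling ligand WNT7A (-1.26 ± 0.30). POU2F2 (-1.18 ± 0.29), FRMD5 (-1.11 ± 0.19), IFFO2 (-1.06 ± 0.24) and the membrane-bound metalloproteinase MMP16 (-0.93 ± 0.19) also fell. Of the 33 glucocorticoid-induced genes, 10 rose (18 over the list alone), such as TSC22D3 (2.12 ± 0.25), ZBTB16 (2.12 ± 0.30) and the thiamine transporter SLC19A2 (1.13 ± 0.18). The set rose (adjusted p = 3.32e-39). SCNN1A, called with every other siRNA condition, changed by 0.37 ± 0.24 here (adjusted p = 1.00). The metallothioneins rose (MT2A 0.94 ± 0.19, MT1E 1.19 ± 0.26; set adjusted p = 4.67e-12), and so did the adipocyte list (2 of 13, adjusted p = 2.37e-08). Of the 17 inflammatory genes LIF fell (2 over the list alone). The set fell (adjusted p = 4.18e-07, but adjusted p = 0.248 with an estimated correlation). The 16 immediate early genes fell as a set with 0 called singly (adjusted p = 0.00839, and adjusted p = 0.708 with an estimated correlation; adjusted p = 0.0636 with the replicate block). TNFRSF11B was the only called member of the 10 osteoblast genes, whose set did not pass (adjusted p = 0.964).

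At an adjusted p under 0.05, 110 genes rose and 23 fell with siHic5siNS, and the groups of all 133 did not overlap. Over all genes the share without overlap was 10.9%, against 10% by chance for unpaired libraries. With the replicate block 653 rose and 676 fell. The chemokine CCL2 (-2.23 ± 0.56, adjusted p = 0.0268 against 0.199 without the block), the growth factor CSF2 (-2.01 ± 0.30, adjusted p = 0.000518 against 0.434), HBEGF (-1.50, adjusted p = 0.0188 against 0.244) and the protease ADAMTS1 (-1.25, adjusted p = 0.00027 against 0.481) were among the falls called only with it. The 20 p53 targets fell as a set only with the block (adjusted p = 0.0208, and adjusted p = 0.242 with an estimated correlation; adjusted p = 0.242 without the block). The count for the dex response with siHic5siNS was 71 without vehicle replicate 2 and 84 without dex replicate 1. With the block, 683 were called without pair 2. With no scaling factors the blocked split was 570 up and 768 down.

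In the libraries labelled siCHD9siNS, dex raised SPINK13 by 5.16 ± 0.53 (adjusted p = 1.87e-06), FAM107A by 3.66 ± 0.79, EDN3 by 3.38 ± 0.73, PDK4, a kinase that inhibits pyruvate dehydrogenase, by 3.33 ± 0.64, and DNER by 3.28 ± 0.40. KDR, the main VEGF receptor of endothelial cells, rose by 3.23 ± 0.56. TNFRSF11B (-1.41 ± 0.35) and FRMD5 (-0.88 ± 0.19) were 2 of the 3 genes that fell; the other carries only a numbered reading-frame name. Of the 33 glucocorticoid-induced genes 9 rose (13 over the list alone; set adjusted p = 1.19e-22), with TIPARP at 1.82 ± 0.24, ZBTB16 at 2.40 ± 0.32 and FKBP5 at 1.72 ± 0.28. MT1E (1.16 ± 0.26) and MT2A (0.78 ± 0.19) rose among the 4 metallothioneins (set adjusted p = 2.75e-07). The 20 steroid receptor and coregulator genes rose as a set (adjusted p = 0.000135, and adjusted p = 0.023 with an estimated correlation). FKBP5 and the p160 coactivators NCOA2 (0.79 ± 0.13) and NCOA3 (0.48 ± 0.10) were called, and 6 over the list alone. The CHD family also rose as a set (adjusted p = 0.00484, and adjusted p = 0.0264 with an estimated correlation). Of its 10 genes 0 were called, and 2 over the list alone. Neither list passed with the replicate block and an estimated correlation (adjusted p = 0.166 for the receptors and coregulators and 0.226 for the CHD family), nor did the metallothioneins (0.0791, against 0.0264 without the block). The inflammatory genes (adjusted p = 0.000613, but adjusted p = 0.512 with an estimated correlation) and the immediate early genes (adjusted p = 0.00275, and adjusted p = 0.672 with an estimated correlation) fell as sets with 0 members called in each. In all 145 genes rose and 3 fell. With the replicate block 1686 rose and 1937 fell. With length and GC offsets added, 966 rose and 1166 fell; the lists were not tested with offsets. The falls called only with the block included OASL, an interferon-induced gene (-1.44 ± 0.15, adjusted p = 8.71e-06 against 0.166), the beta-synuclein gene SNCB (-1.20, adjusted p = 0.000738 against 0.0508) and the channel TRPV3 (-1.16, adjusted p = 0.000496 against 0.261). The count for the dex response with siCHD9siNS was 26 and 72 without vehicle replicate 1 or 2, and 55, 82 and 88 without dex replicate 1, 2 or 3. The blocked count was 1061 without pair 1. With no scaling factors the blocked split was 2192 up and 1176 down.

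**Figure D2:**
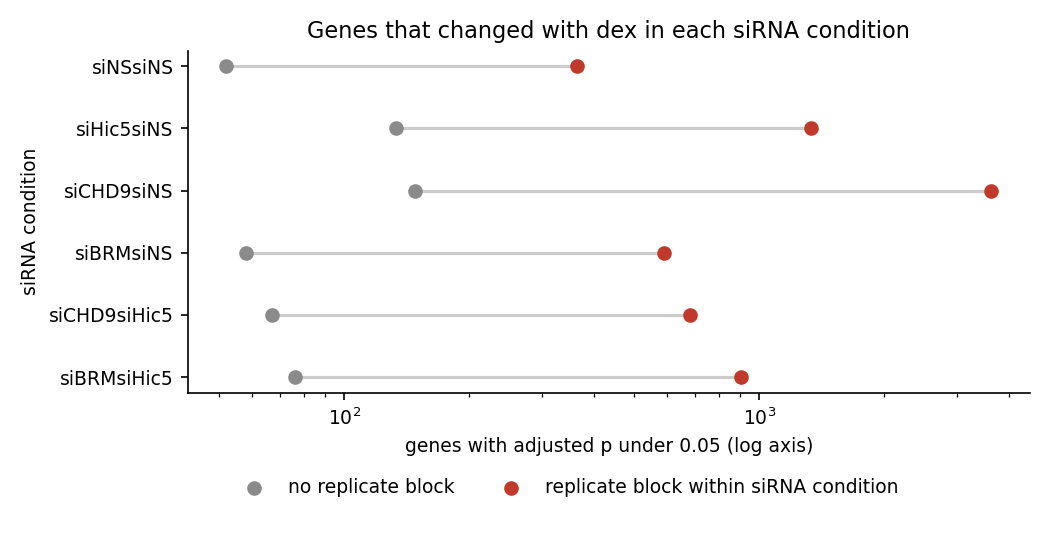
Number of genes with an adjusted p under 0.05 for dex against vehicle in each siRNA condition, on a log axis. Grey points are from the fit without a replicate block and red points from the fit with the block within siRNA condition; with siNSsiNS the count is 52 without and 363 with the block, and with siCHD9siNS 148 and 3623.

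With BRM depleted, dex raised TRIM49D2 by 4.21 ± 0.84 (adjusted p = 0.0142), SPINK13 by 3.47 ± 0.45 (adjusted p = 0.000314), FAM107A by 2.58 ± 0.56, the phosphatase and actin regulator PHACTR3 by 2.43 ± 0.52 and KLF15 by 2.28 ± 0.38. Of the 33 glucocorticoid-induced genes 10 rose (17 over the list alone; set adjusted p = 4.87e-51), for example TSC22D3 (1.71 ± 0.25), TIPARP (1.53 ± 0.24), SCNN1A (1.36 ± 0.24) and FKBP5 (1.33 ± 0.28). MT2A (0.96 ± 0.19), MT1E (1.19 ± 0.26) and MT1X (0.99 ± 0.22) rose, and so did the adipocyte list (2 of 13, adjusted p = 3.16e-07, but adjusted p = 0.0913 with the block and an estimated correlation). The inflammatory genes fell as a set with 0 of 17 called (adjusted p = 0.00119, but adjusted p = 0.396 with an estimated correlation). The channel list rose with SCNN1A called (adjusted p = 0.0267, and adjusted p = 0.187 with an estimated correlation). Immediate early genes did not pass as a set (adjusted p = 0.13). In edgeR 58 genes rose and 0 fell (534 at an unadjusted p under 0.05), 55 of the 58 without overlap of the groups. Over all genes the share without overlap was 5.62%, against 10% by chance for unpaired libraries. With the block 357 rose and 231 fell, among the latter TGFBI, an extracellular matrix protein induced by TGF-beta (-0.81 ± 0.16, adjusted p = 0.00959 against 0.931), and the galactosyltransferase B3GALT5 (-0.81, adjusted p = 0.000511 against 0.117). The count for the dex response with siBRMsiNS was 17 and 28 without vehicle replicate 2 or 3 and 29 and 25 without dex replicate 1 or 2. Without pair 1 the blocked count was 189. With TMM factors the blocked split was 332 up and 302 down.

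In the libraries labelled siCHD9siHic5, dex raised SPINK13 by 5.99 ± 0.60 (adjusted p = 1.52e-06), the cytochrome P450 gene CYP4B1 by 4.53 ± 0.65, CACNA1I by 4.36 ± 0.51, PDK4 by 3.80 ± 0.66, KDR by 3.71 ± 0.61 and DNER by 3.52 ± 0.39. The 4 genes that fell were WNT7A (-1.45 ± 0.30), B3GALT5 (-1.26 ± 0.26), FRMD5 (-0.91 ± 0.19) and NR2F2, the orphan nuclear receptor COUP-TFII (-0.56 ± 0.13). Of the 33 glucocorticoid-induced genes 8 rose (15 over the list alone; set adjusted p = 1.48e-49), such as ZBTB16 (2.84 ± 0.33), FKBP5 (1.90 ± 0.28), TIPARP (1.81 ± 0.24) and TSC22D3 (1.56 ± 0.25). MT2A (1.13 ± 0.19), MT1E (1.34 ± 0.26) and MT1X (0.98 ± 0.22) rose. The adipocyte list rose with ZBTB16 called (adjusted p = 5.1e-05, but adjusted p = 0.121 with the block and an estimated correlation). The inflammatory genes (adjusted p = 3.32e-05, but adjusted p = 0.436 with an estimated correlation) and the immediate early genes (adjusted p = 0.000612, and adjusted p = 0.63 with an estimated correlation) fell as sets with 0 members called. In total 63 genes rose and 4 fell, and 473 rose and 207 fell with the block. With the block the p53 targets also fell as a set (adjusted p = 0.0382, and adjusted p = 0.369 with an estimated correlation; adjusted p = 0.277 without the block). The count for the dex response with siCHD9siHic5 was 39 and 43 without vehicle replicate 1 or 3 and 39 without dex replicate 3. The blocked count was 312 without pair 3 and 405 without pair 2.

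With Hic-5 and BRM both depleted, dex raised TRIM49D2 by 3.87 ± 0.92 (adjusted p = 0.0467), CDH15 by 3.78 ± 0.65 (adjusted p = 0.00165), the lipid droplet gene CIDEC by 3.46 ± 0.80 and SPINK13 by 3.27 ± 0.45 (adjusted p = 0.000232). NR2F2 was the 1 gene that fell (-0.56 ± 0.13, adjusted p = 0.0488). Of the 33 glucocorticoid-induced genes 8 rose (17 over the list alone; set adjusted p = 2.6e-37), among them TSC22D3 (2.01 ± 0.25), ZBTB16 (1.98 ± 0.32), TIPARP (1.76 ± 0.24) and FKBP5 (1.31 ± 0.28). The metallothioneins rose as a set with 0 of 4 called (4 over the list alone; adjusted p = 2.31e-10). The adipocyte list rose with ZBTB16 and KLF15 (1.92 ± 0.41) called (adjusted p = 0.000785, but adjusted p = 0.196 with the block and an estimated correlation). The inflammatory set fell with 0 of 17 called and 2 over the list alone (adjusted p = 4.32e-10, but adjusted p = 0.0609 with an estimated correlation), as did the immediate early genes (adjusted p = 1.84e-05, and adjusted p = 0.271 with an estimated correlation). Sets that rose with no member called, or with FKBP5 alone, were the circadian clock (adjusted p = 0.0176, but adjusted p = 0.252 with an estimated correlation), the CHD family (adjusted p = 0.0181, and adjusted p = 0.0609 with an estimated correlation) and the steroid receptors and coregulators (adjusted p = 0.00204, and adjusted p = 0.0565 with an estimated correlation). In all 75 genes rose and 1 fell, 74 of these 76 without overlap of the groups. Over all genes the share without overlap was 9.05%, against 10% by chance for unpaired libraries. With the block 644 rose and 261 fell, including the apoptosis inhibitor BCL2A1 (-1.48, adjusted p = 0.000892 against 0.112) and the endothelial proteoglycan ESM1 (-1.46, adjusted p = 0.00446 against 0.366). With TMM factors the blocked split was 567 up and 343 down, and with length and GC offsets 523 up and 445 down. The count for the dex response with siBRMsiHic5 was 37 and 31 without vehicle replicate 2 or 3 and 45 and 39 without dex replicate 1 or 2. Without pair 3 the blocked count was 446.

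Genes that rose with dex were shared between conditions that have no library in common. Of the genes that rose with siNSsiNS, 38 also rose with siHic5siNS (0.377 expected if independent), 38 with siCHD9siNS (0.497 expected) and 43 with siBRMsiNS (0.199 expected). The set that rose in all 6 conditions held 16 genes: TSC22D3, FKBP5, ZBTB16, TIPARP, SPINK13, CACNA1I, DNER, CLVS2, IP6K3, FGD4, ARMC12, RIMBP2, MORC1, SLC46A3, SLC6A19 and ZNF189. With the replicate block 106 genes rose and 12 fell in all 6 conditions. FKBP5 rose by between 1.31 ± 0.28 (siBRMsiHic5) and 1.90 ± 0.28 (siCHD9siHic5), and ZBTB16 by between 1.55 ± 0.30 (siBRMsiNS) and 2.84 ± 0.33 (siCHD9siHic5).

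**Figure D3:**
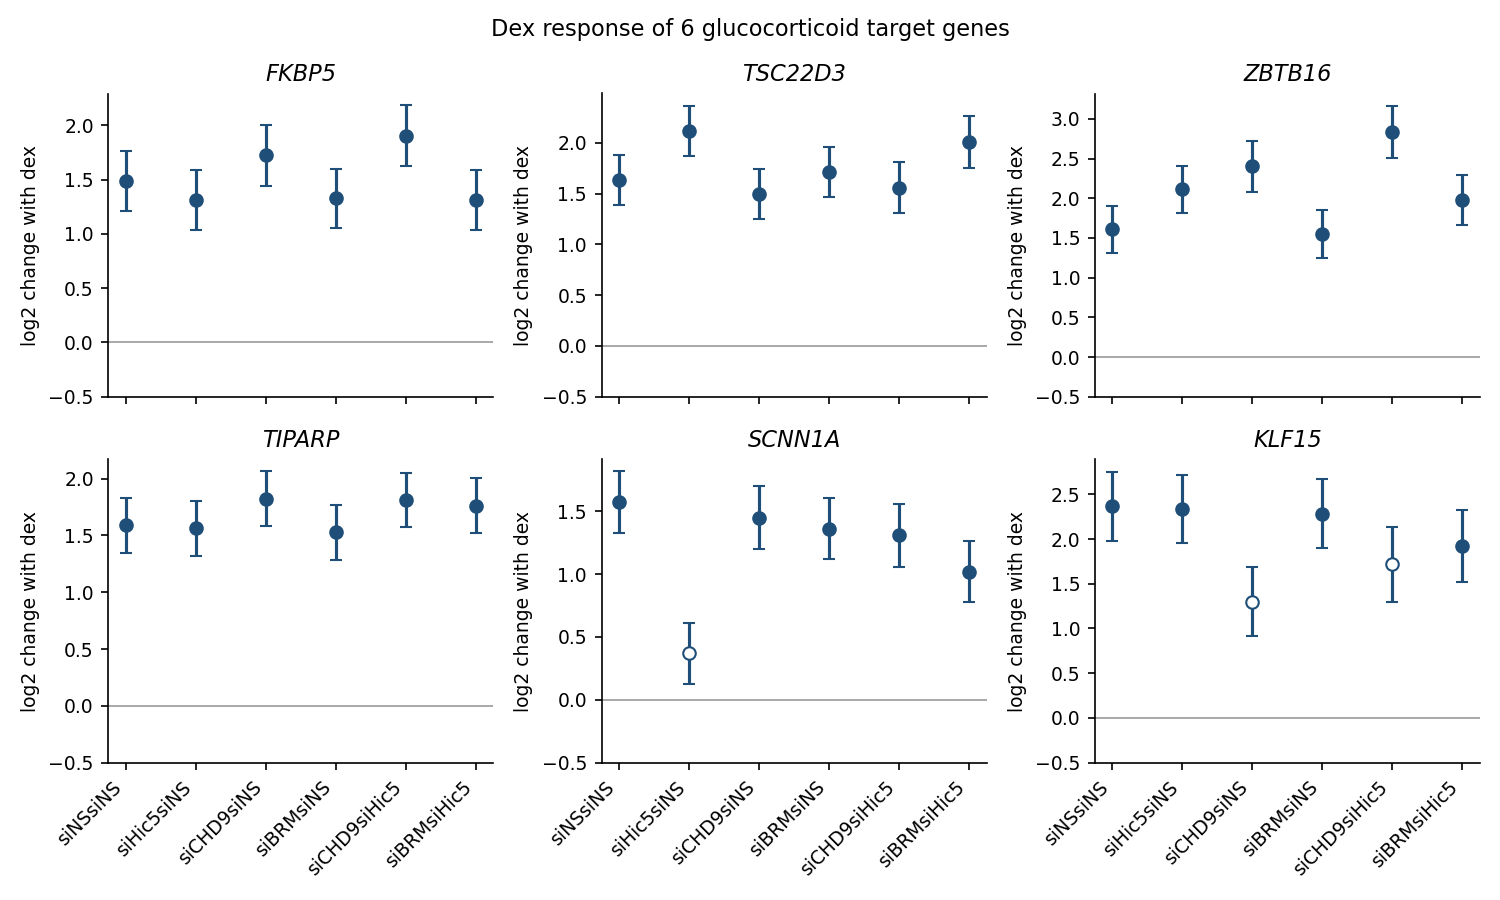
Log2 change with dex of FKBP5, TSC22D3, ZBTB16, TIPARP, SCNN1A and KLF15 in the 6 siRNA conditions, with bars for the standard error (n = 3 against 3). Filled points have an adjusted p under 0.05 without the replicate block and open points do not; SCNN1A changes by 0.37 ± 0.24 with siHic5siNS and by 1.57 ± 0.25 with siNSsiNS.

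Whether the dex response differed between siRNA conditions was tested as a difference of responses. Without the block, 0 genes differed between siHic5siNS and siNSsiNS in edgeR (125 at an unadjusted p under 0.05; DESeq2 0, limma 0). With the block 20 had a higher and 7 a lower response with Hic-5 depleted. The higher responses included CDH15 (2.46 ± 0.47, adjusted p = 0.0462), RASGRP2 (2.23 ± 0.40, adjusted p = 0.0262), the lysophospholipase PNPLA7 (1.33 ± 0.23, adjusted p = 0.0172), the calcium-activated chloride channel ANO2 (1.00 ± 0.16, adjusted p = 0.00702) and the small GTPase RHOB (0.98 ± 0.17, adjusted p = 0.0236). RASGRP2 had a lower vehicle level with siHic5siNS than with siNSsiNS (0.624 ± 0.310 against 2.49 ± 0.716 CPM). Its dex levels were near each other (8.97 ± 0.966 and 7.41 ± 1.27 CPM). CDH15 differed mostly with dex (16.4 ± 2.76 against 4.36 ± 0.896 CPM, vehicle 1.24 ± 0.903 and 1.77 ± 0.662 CPM). How far vehicle levels account for such differences was not tested. The lower ones included UNC80 (-1.35 ± 0.24), SCNN1A (-1.20 ± 0.16, adjusted p = 0.0046), the interleukin 1 receptor accessory protein IL1RAP (-0.69 ± 0.11) and GPR137B (-0.61 ± 0.08, adjusted p = 0.00176). Without the block the adjusted p of each of these genes was 1.00. None of the 21 gene lists differed between siHic5siNS and siNSsiNS (smallest adjusted p = 0.235 without and 0.0869 with the block). The blocked count was 7 without siNSsiNS pair 1, and the split was 12 higher and 9 lower with no scaling factors.

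Between the libraries labelled siCHD9siNS and siNSsiNS, the response of 1 gene differed without the block: CDH20, a cadherin with a low level here, rose by 2.72 ± 0.37 with siNSsiNS and changed by -0.27 ± 0.33 with siCHD9siNS (difference -2.99 ± 0.50, adjusted p = 0.0311). DESeq2 called 23 genes, and limma with a pseudocount of 0.5, the filter on mean CPM, the block over all groups and the fit of the compared groups alone called 0. With the block 340 genes had a higher and 286 a lower response with siCHD9siNS. FLG2 (1.62 ± 0.44, adjusted p = 0.0428) and the platelet receptor subunit GP1BA (1.33 ± 0.35, adjusted p = 0.0375) had higher responses. OASL (-1.27 ± 0.22, adjusted p = 0.00937), the epithelial transcription factor EHF (-1.41 ± 0.37, adjusted p = 0.0392), the atrophy-related ubiquitin ligase subunit FBXO32 (-0.97 ± 0.20, adjusted p = 0.0194) and the SWI/SNF subunit gene DPF3 (-0.74 ± 0.20, adjusted p = 0.0433) had lower ones. Each of these 6 genes had an adjusted p = 1.00 without the block. The CHD family (0 of 10 called; adjusted p = 0.000323, and adjusted p = 0.0102 with an estimated correlation) and the steroid receptors and coregulators (0 of 20 called, 3 over the list alone; adjusted p = 5.75e-05, and adjusted p = 0.0102 with an estimated correlation) had higher responses as sets with siCHD9siNS. With the block and an estimated correlation the adjusted p of each of these 2 lists was 0.212. The siCHD9siNS difference correlated with transcript length (Spearman rho = 0.481) and GC (rho = -0.242), and the lists were not tested with offsets. The blocked count of 626 was 2, 79 and 715 without siCHD9siNS pair 1, 2 or 3 and 0, 628 and 15 without siNSsiNS pair 1, 2 or 3. With length and GC offsets it was 121. With no scaling factors the blocked count was 500 (346 higher and 154 lower), and with TMM 569 (431 and 138).

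Between siBRMsiNS and siNSsiNS, 0 genes differed in edgeR without the block (25 at an unadjusted p under 0.05, DESeq2 0, limma 0) and 0 with it (597 at an unadjusted p under 0.05). Both unadjusted counts lie under a share of 0.05 of the 15179 tested genes, so neither is a sign of a difference. The count without the block leaves the pairing out, so it is no evidence of absence either. The 16 immediate early genes had a higher response as a set, with 0 called (adjusted p = 0.0231, but adjusted p = 0.961 with an estimated correlation and 0.237 with the block).

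The conditions labelled siCHD9siHic5 and siBRMsiHic5 were compared with siHic5siNS. For the libraries labelled siCHD9siHic5, 0 genes differed without the block (116 at an unadjusted p under 0.05; DESeq2 1, limma 1). With the block 8 responses were higher and 12 lower. SCNN1A (0.93 ± 0.17, adjusted p = 0.0416), FKBP5 (0.62 ± 0.11, adjusted p = 0.029) and the neuronal microtubule protein MAP2 (0.83 ± 0.16, adjusted p = 0.0416) responded more. RP1L1 (-2.23 ± 0.41, adjusted p = 0.0416), the inducible nitric oxide synthase NOS2 (-1.70 ± 0.33, adjusted p = 0.0416), PNPLA7 (-1.47 ± 0.23, adjusted p = 0.0209), the placental growth factor PGF (-1.45 ± 0.26, adjusted p = 0.0397) and ANO2 (-0.86 ± 0.17, adjusted p = 0.045) responded less. For siBRMsiHic5, 0 genes differed without the block (301 at an unadjusted p under 0.05; DESeq2 1, limma 0). With the block 20 responses were higher and 10 lower. The metalloproteinase ADAMTS7 (1.24 ± 0.16, adjusted p = 0.00302), UNC80 (1.20 ± 0.23, adjusted p = 0.0441) and SERTAD4 (0.77 ± 0.12, adjusted p = 0.01) responded more. PNPLA7 (-1.38 ± 0.24, adjusted p = 0.0205), the organic anion transporter SLCO4A1 (-1.05 ± 0.15, adjusted p = 0.00879), the aldo-keto reductase AKR1C1 (-1.36 ± 0.27, adjusted p = 0.0455) and ANO2 (-0.83 ± 0.16, adjusted p = 0.0361) responded less. Each of these genes had an adjusted p = 1.00 without the block. No list differed with siCHD9siHic5 (smallest adjusted p = 0.166). The CHD family (adjusted p = 0.000939, and adjusted p = 0.019 with an estimated correlation) and the steroid receptors and coregulators (adjusted p = 0.000344, and adjusted p = 0.0214 with an estimated correlation) had higher responses as sets with siBRMsiHic5, with 0 members called in each. With the block and an estimated correlation these were 0.296 and 0.498. The siBRMsiHic5 difference correlated with length (Spearman rho = 0.343) and GC (rho = -0.259), and the lists were not tested with offsets. The 2 comparisons share the siHic5siNS libraries, so a gene found in both was not counted as shared. The blocked count for siCHD9siHic5 was 1 without siHic5siNS pair 2 and at most 10 without any other pair, and that for siBRMsiHic5 was 2 without siBRMsiHic5 pair 3 and 177 without siHic5siNS pair 3. With TMM factors the siBRMsiHic5 count was 12 (7 higher and 5 lower), with no factors 64 (52 and 12), and with length and GC offsets 13 (5 and 8, of which 9 were among the 30). For siCHD9siHic5 the split was 8 higher and 7 lower with no factors and 7 and 17 with the offsets.

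Block genes were taken as those called with siHic5siNS and not with siNSsiNS, with an unadjusted p under 0.05 for a larger response in the same direction. Without the replicate block there were 38, 28 that rose and 10 that fell with siHic5siNS. Among them the tyrosine phosphatase PTPN1 rose by 0.73 ± 0.12 with siHic5siNS and changed by 0.19 ± 0.12 with siNSsiNS, and PNPLA7 gave 1.37 ± 0.24 and 0.02 ± 0.24. The vasodilator peptide ADM (1.28 ± 0.28 against 0.39 ± 0.27), NOS2 (1.71 ± 0.34 against 0.32 ± 0.33), the desmosomal protein PKP2 (1.47 ± 0.26 against 0.54 ± 0.26) and VIPR2, a receptor of vasoactive intestinal peptide (2.26 ± 0.46 against 0.75 ± 0.43), rose as well. PTPN1, ADM and PKP2 lie outside the rule for named genes and were chosen after their values were seen. Of those that fell, RGS16 gave -1.69 ± 0.35 with siHic5siNS and -0.38 ± 0.39 with siNSsiNS, the cell cycle inhibitor CDKN2B -0.81 ± 0.20 and -0.13 ± 0.21, and the growth factor receptor FGFR2 -0.62 ± 0.15 and -0.14 ± 0.15. With the paired siRNAs PNPLA7 changed by -0.12 ± 0.24 (siCHD9siHic5) and -0.03 ± 0.24 (siBRMsiHic5), MAP7D2 by 0.04 ± 0.48 and 0.58 ± 0.39 against 2.25 ± 0.49 with siHic5siNS, and ZBTB20 by -0.08 ± 0.24 and 0.22 ± 0.26 against -1.28 ± 0.25. Others still responded: RASGRP2 rose by 3.34 ± 0.56 and 2.73 ± 0.50 and CDH15 by 3.30 ± 0.63 and 3.78 ± 0.65. With siNSsiNS RASGRP2 changed by 1.58 ± 0.45 and CDH15 by 1.29 ± 0.56 (neither called). Neither gene is in the class with the replicate block. The mirror class, called with siNSsiNS and not with siHic5siNS and with an unadjusted p under 0.05 for a smaller response with siHic5siNS, held 5 genes that rose with siNSsiNS. It held 47 with the replicate block (35 up and 12 down), of which 4 were among the 5. The 5 were SCNN1A, CDH20, the estrogen-regulated gene GREB1 (1.28 ± 0.29 with siNSsiNS and 0.20 ± 0.28 with siHic5siNS), MUM1L1 (1.63 ± 0.37 and 0.47 ± 0.36) and a transcript without a gene name.

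The median response of the 38 block genes, signed by their direction with siHic5siNS, was 1.45 with siHic5siNS, 0.39 with siNSsiNS, 0.33 with siCHD9siNS, 0.49 with siBRMsiNS, 0.41 with siCHD9siHic5 and 0.61 with siBRMsiHic5. The siHic5siNS and siNSsiNS values rest on the libraries that chose the genes. Genes were therefore chosen on 2 replicate numbers and measured in the left-out number, which gave 8, 7 and 33 genes. Their mean median response was then 1.24 ± 0.30 (SD, n = 3) with siHic5siNS and 0.79 ± 0.52 with siNSsiNS (exact paired permutation p = 0.5), which was lower in 2 of 3 numbers and not in number 1 (1.38 against 1.36). It was 0.54 ± 0.06 with siCHD9siHic5, lower than with siHic5siNS in 3 of 3 numbers (exact paired permutation p = 0.25, the smallest that 3 pairs allow). It was 0.73 ± 0.35 with siBRMsiHic5, also lower in 3 of 3 (exact paired permutation p = 0.25). Genes called with and without Hic-5, treated in the same way (2, 12 and 17 genes), gave 1.70 ± 0.31 with siHic5siNS, 1.37 ± 0.58 with siCHD9siHic5 and 1.42 ± 0.23 with siBRMsiHic5. With the replicate block the class held 456 genes (183 up and 273 down), of which 28 were in the class without it. The held-out response was then 0.34 ± 0.06 with siHic5siNS, 0.19 ± 0.04 with siCHD9siHic5 (exact paired permutation p = 0.25) and 0.18 ± 0.15 with siBRMsiHic5 (exact paired permutation p = 0.5). Without siHic5siNS vehicle replicate 2 the block genes numbered 22, and without replicate number 1 or 2 in all groups 8 and 7. The blocked count was 253 without siHic5siNS pair 2.

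**Figure D4:**
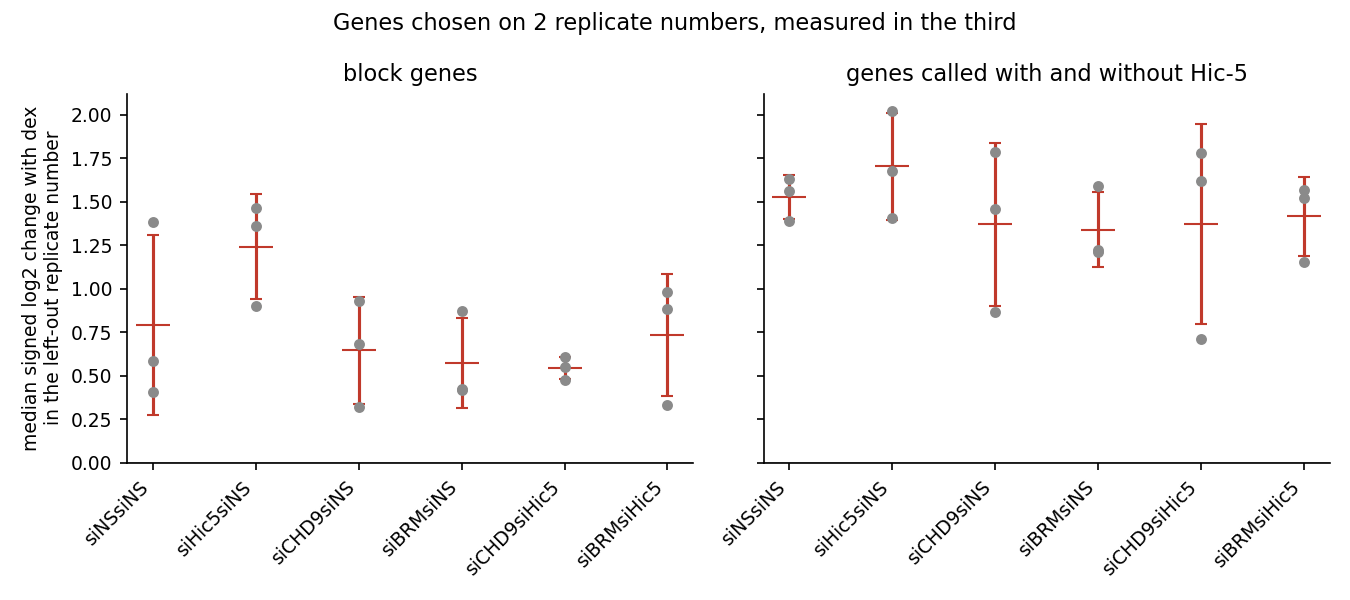
Median signed log2 change with dex of genes chosen on 2 replicate numbers and measured in the left-out number, for block genes (left) and for genes called with and without Hic-5 (right), without the replicate block. Each point is 1 left-out number, marks are means and bars SD (n = 3); block genes average 1.24 with siHic5siNS and 0.54 with siCHD9siHic5.

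The last question was how the siRNAs changed the vehicle level of all genes. These 5 comparisons share the siNSsiNS vehicle libraries, so their counts are not independent of each other. With Hic-5 depleted, MGP, the matrix Gla protein that inhibits calcification (6.19 ± 1.10, adjusted p = 3.69e-05), the receptor CD300LB (5.97 ± 0.69) and the secreted glycoprotein CHI3L1 (5.49 ± 0.92) were among the largest rises. The myosin light chains MYL4 (-7.50 ± 0.75, from 22.9 ± 4.7 to 0.125 ± 0.088 CPM) and MYL1 (-5.30 ± 0.66) fell, as did the chloride channel protein CLIC5 (-4.77 ± 1.01) and KY (-4.72 ± 0.74). Of 30 proliferation genes 27 fell and 0 rose (28 fell over the list alone), such as cyclin B1 (CCNB1, -1.81 ± 0.17), AURKA (-1.88 ± 0.21) and the anaphase activator CDC20 (-2.39 ± 0.28). The set gave an adjusted p = 8.06e-12, but adjusted p = 0.636 with an estimated correlation. Of 23 interferon response genes 15 fell and 3 rose (adjusted p = 0.00335, but adjusted p = 0.636 with an estimated correlation), with PARP9 at -2.13 ± 0.19 and OAS3 at -2.00 ± 0.22. Of 19 unfolded protein and amino acid stress genes 10 rose and 2 fell (adjusted p = 0.0195, but adjusted p = 0.636 with an estimated correlation), with HERPUD1 at 1.90 ± 0.13 and TRIB3 at 1.76 ± 0.27. Of 21 cholesterol synthesis genes 14 rose and 1 fell (adjusted p = 0.0195, but adjusted p = 0.874 with an estimated correlation), INSIG1 by 2.49 ± 0.39. MSMO1 fell by 1.48 on the log2 scale. Of 26 matrix genes 15 rose and 5 fell (adjusted p = 0.0304, but adjusted p = 0.636 with an estimated correlation), with fibronectin (FN1) at 2.65 ± 0.36, tenascin C (TNC) at 2.29 ± 0.29 and the collagen crosslinker LOXL2 at -2.36 ± 0.19.

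Other lists moved in both directions or did not pass as sets with siHic5siNS. Of 31 focal adhesion genes 13 rose and 3 fell, the latter including the kindlin gene FERMT2 (-2.58 ± 0.28) and TGFB1I1 itself (set adjusted p = 0.169). FKBP5 (1.49 ± 0.28) and MT2A (1.27 ± 0.19) were among 9 of 33 glucocorticoid-induced genes that rose without hormone (4 fell; set adjusted p = 0.3). The sets of TGF-beta targets (adjusted p = 0.358), SWI/SNF subunits, CHD family and osteoblast genes (each adjusted p = 0.759), and adipocyte genes (adjusted p = 0.209) did not pass. Among markers of other cell types, 3 of 7 epithelial markers rose, led by KRT14 (3.09 ± 0.75), and 1 fell (set adjusted p = 0.725). Of 6 haematopoietic markers LCP1 rose (1.49 ± 0.48) and CORO1A fell (-0.89 ± 0.33; set adjusted p = 0.949). Without hormone, 3936 genes were higher and 4130 lower than with siNSsiNS. The groups did not overlap for 7743 of the 8066, and for 61.2% of all genes, against 10% by chance.

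In the vehicle libraries labelled siCHD9siNS, the cornified envelope gene LCE1C (4.41 ± 0.64, adjusted p = 1.14e-05), the myeloid receptor TREM2 (4.20 ± 0.63) and CHI3L1 (3.35 ± 0.89) rose. OLFML2A (-4.04 ± 0.30, adjusted p = 2.94e-10), FAM107A (-3.51 ± 0.80), the apolipoprotein APOB (-3.30 ± 0.45) and the NMDA receptor subunit GRIN2B (-3.19 ± 0.59) fell. Of 20 p53 targets 12 rose and 0 fell (15 rose over the list alone), such as the death receptor FAS (1.34 ± 0.20), TP53I3 (0.99 ± 0.19) and BAX (0.80 ± 0.17). The set gave an adjusted p = 8.96e-06, but adjusted p = 0.717 with an estimated correlation. Of 19 stress genes 10 rose, including ATF4 (1.57 ± 0.15), PHGDH, an enzyme of serine synthesis (1.34 ± 0.17), and CHAC1 (2.53 ± 0.34). The set gave an adjusted p = 8.96e-06, but adjusted p = 0.238 with an estimated correlation. Of 23 interferon response genes 10 fell, among them IFIT2 (-3.23 ± 0.45) and IFIT1 (-1.76 ± 0.27). The set gave an adjusted p = 0.00734, but adjusted p = 0.768 with an estimated correlation. With a replicate block over all groups, 1 list passed for this comparison at an estimated correlation, against 0 without that block. ZBTB16 (-2.01 ± 0.32) and SCNN1A (-1.50 ± 0.25), which dex raises, were lower without hormone, as was NCOA2 (-1.17 ± 0.13). In total 2389 genes were higher and 2509 lower. These changes correlated with transcript length (Spearman rho = -0.296), while those of siCHD9siHic5 against siHic5siNS gave rho = -0.0593, and the vehicle lists were not tested with offsets. The count for siCHD9siNS against siNSsiNS with vehicle was 3164 without siCHD9siNS vehicle replicate 1.

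With BRM depleted, the retinol dehydrogenase DHRS9 (2.83 ± 0.78), the hemidesmosomal collagen COL17A1 (2.46 ± 0.48, adjusted p = 0.00744), the GDNF receptor GFRA1 (2.42 ± 0.67) and the cytokine IL24 (2.35 ± 0.62) rose with vehicle. SEC16B (-2.27 ± 0.47), the dopamine receptor DRD1 (-1.96 ± 0.52), the cholesterol exporter ABCA1 (-1.84 ± 0.42) and IGFBP7 (-1.67 ± 0.43) fell. Of 20 SWI/SNF subunit genes 3 fell, SMARCA2, ARID1A (-0.57 ± 0.17) and ARID2 (-0.44 ± 0.13), and 2 rose, DPF3 (1.57 ± 0.30) among them (set lower, adjusted p = 0.0079, and adjusted p = 0.0306 with an estimated correlation). This list holds the siRNA target SMARCA2 (-1.79 ± 0.18). Of 10 CHD family genes CHD7 fell (-0.49 ± 0.14; 3 fell over the list alone; adjusted p = 0.0079, and adjusted p = 0.0457 with an estimated correlation). With a replicate block over all groups and an estimated correlation the SWI/SNF list kept its call (adjusted p = 0.0259) and the CHD family lost it (adjusted p = 0.106). The circadian set was lower with TEF called (-0.51 ± 0.16; adjusted p = 0.0079, but adjusted p = 0.282 with an estimated correlation), and the interferon set with 0 of 23 called (adjusted p = 0.0174, but adjusted p = 0.822 with an estimated correlation). In total 649 genes were higher and 336 lower, and 839 of the 985 did not overlap (22.7% of all genes, 10% by chance). The count for siBRMsiNS against siNSsiNS with vehicle was 13, 43 and 19 without siNSsiNS vehicle replicate 1 or 2 or siBRMsiNS vehicle replicate 3, and 2366 without siBRMsiNS vehicle replicate 1.

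In the vehicle libraries labelled siCHD9siHic5, TREM2 (5.17 ± 0.63), the transcription factor TFEC (4.50 ± 0.41) and heme oxygenase 1 (HMOX1, 4.44 ± 0.50) rose. MYL4 (-7.11 ± 0.71), the calpain CAPN6 (-6.35 ± 0.58) and the apolipoprotein APOL3 (-6.17 ± 0.64) fell. Of 20 p53 targets 16 rose and 0 fell (XPC 1.62 ± 0.20, FAS 1.65 ± 0.21; set adjusted p = 3.7e-06, but adjusted p = 0.808 with an estimated correlation). Of 23 interferon response genes 16 fell and 0 rose (IFIT1 -3.47 ± 0.29, IFIT2 -4.61 ± 0.50; set adjusted p = 5.32e-07, but adjusted p = 0.574 with an estimated correlation). Of 30 proliferation genes 20 fell and 2 rose, with TOP2A at -1.36 ± 0.15 (set adjusted p = 0.00703, but adjusted p = 0.914 with an estimated correlation). Of 19 stress genes 10 rose and 3 fell, with ATF4 at 1.52 ± 0.15 (set adjusted p = 0.00165, but adjusted p = 0.574 with an estimated correlation). SMAD6, an inhibitor of BMP signalling, fell by 4.98 on the log2 scale and ACTA2, smooth muscle actin, rose by 2.40 ± 0.26. In total 3589 genes were higher and 4386 lower than with siNSsiNS.

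With Hic-5 and BRM both depleted, DHRS9 (5.27 ± 0.79), the stromelysin MMP3 (4.96 ± 1.01) and GFRA1 (4.11 ± 0.69) rose with vehicle. CRYBA4 (-5.91 ± 1.19), MYL4 (-4.99 ± 0.61) and the stem cell receptor LGR5 (-4.46 ± 0.69) fell. Of 17 circadian clock genes 14 fell and 0 rose, led by TEF (-1.33 ± 0.16) and DBP (-1.63 ± 0.26; set adjusted p = 0.000331, but adjusted p = 0.0971 with an estimated correlation). Of 10 CHD family genes 8 fell (9 over the list alone), such as CHD6 (-1.10 ± 0.11), CHD2 (-1.12 ± 0.19) and CHD9 (set adjusted p = 0.00165, and adjusted p = 0.0328 with an estimated correlation). That call was lost with a replicate block over all groups and an estimated correlation (adjusted p = 0.0722). Of 20 SWI/SNF subunit genes 12 fell and 4 rose, with ARID1A at -1.40 ± 0.17 and DPF3 at 1.98 ± 0.31 (set adjusted p = 0.0254, but adjusted p = 0.0882 with an estimated correlation). Of 20 steroid receptors and coregulators 10 fell and 1 rose, including CREBBP (-0.75 ± 0.08), EP300 (-0.75 ± 0.12) and the corepressor NCOR1 (-0.70 ± 0.11; set adjusted p = 0.00693, but adjusted p = 0.0971 with an estimated correlation). The interferon response fell with 17 of 23 genes, BST2 by 3.66 on the log2 scale (adjusted p = 5.48e-05, but adjusted p = 0.252 with an estimated correlation). Of 21 cholesterol synthesis genes 14 rose and 0 fell, HMGCS1 by 1.16 ± 0.26 (adjusted p = 0.00693, but adjusted p = 0.872 with an estimated correlation). Of 19 stress genes 9 rose and 2 fell (adjusted p = 0.0173, but adjusted p = 0.483 with an estimated correlation). In total 3692 genes were higher and 3738 lower than with siNSsiNS. The vehicle changes with siBRMsiHic5 against siHic5siNS and with siBRMsiNS against siNSsiNS, which share no library, correlated across genes (Pearson r = 0.466, Spearman rho = 0.458). So did those with siCHD9siHic5 against siHic5siNS and siCHD9siNS against siNSsiNS (Pearson r = 0.526, Spearman rho = 0.504). The crossed pairs gave Pearson r = 0.00262 and 0.08 (Spearman rho = 0.0238 and 0.163). RNA28S5, a ribosomal transcript, took 3.44 to 7.51% of the counts of both replicate 3 libraries of siHic5siNS, siBRMsiNS and siBRMsiHic5. In replicate 2 it took 3.95% (vehicle) and 1.92% (dex) with siBRMsiNS and 4.82% and 4.47% with siBRMsiHic5, and in vehicle replicate 3 of siNSsiNS 5.46%, against 0.324 to 0.868% in all libraries labelled with siCHD9.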

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

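The bounds used in this part were written before the result was seen, but the patterns they weigh, and the fit with the replicate block, were picked after the first counts were known. No prediction was written for the exact paired permutation p, or for r without single replicate numbers or without the length and GC trend. The same holds for the TGFB1I1 and SMARCA2 levels and, in the third pattern, for the log2 differences and the siCHD9siNS shares.

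Several values stood out because an effect differed between groups. With the block within siRNA condition, the dex response differed from that with siNSsiNS for 27 genes with siHic5siNS and 626 genes in the libraries labelled siCHD9siNS, and from that with siHic5siNS for 20 genes with siCHD9siHic5 and 30 genes with siBRMsiHic5. Without the block the count for siCHD9siNS was 1. The effect of the siCHD9 label on the CHD9 transcript differed by 1.41 on the log2 scale between cells with and without siHic5 among vehicle libraries (adjusted p = 0.000305) and by 1.11 with dex (adjusted p = 0.00349). Over all genes, the effect of the siCHD9 label differed with siHic5 for 3222 genes with vehicle and 2592 with dex, and the effect of siBRM for 3179 and 2849. None of these interactions had been asked about in the comparisons of the report except the first 5.

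The first pattern weighed was the large number of genes with a different dex response in the libraries labelled siCHD9siNS. Higher responses sat on long transcripts (median 8.81 kb) and lower ones on short transcripts (median 1.87 kb, all genes 3.59 kb), and the differences correlated with length (Spearman rho = 0.481). With length and GC offsets the count was 121, as a length or GC bias would give, although such offsets can also remove a real effect that follows length. The blocked count was 2, 79 and 715 without siCHD9siNS pair 1, 2 or 3 and 0, 628 and 15 without siNSsiNS pair 1, 2 or 3, so fewer pairs did not by themselves lower it, but more than 1 pair did when left out. Whether single pairs deviate, and whether a biological difference lies beneath the remaining genes, stays open.

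The second pattern was the CHD9 transcript, which was higher in the libraries labelled siCHD9siHic5 than in those labelled siHic5siNS. Scaling could not account for it: the lowest log2 change under TMM, median-ratio and total-count scaling was 0.84. The vehicle changes of siCHD9siHic5 against siHic5siNS and of siCHD9siNS against siNSsiNS correlated with r = 0.526 across genes, and with r = 0.545 once the length and GC trend was taken out, against r = 0.00262 and 0.08 for the crossed pairs with siBRM, so the libraries labelled siCHD9siHic5 carry part of the change seen with siCHD9siNS. TGFB1I1 at 26.2% of control and SMARCA2 at 117% (adjusted p = 0.259) also ran as that label says. With siHic5siNS they stood at 24.8% and 118%, so they cannot tell siCHD9siHic5 from siHic5siNS. They argue only against an exchange with groups that lack siHic5 or carry siBRM. Over all libraries r met the bound of 0.5 set beforehand. It was 0.512, 0.530 and 0.491 without replicate number 1, 2 or 3, for which no bound was written. An exchange of the whole siCHD9siHic5 and siHic5siNS groups would reverse the sign of r, so these values argue against it. Other errors of labelling stay open. What raised the CHD9 transcript was not tested, and protein was not analysed here.

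The third pattern was the smaller dex response of block genes with siCHD9siHic5 and siBRMsiHic5 than with siHic5siNS. For siCHD9siHic5 the held-out response was 0.438 of that with siHic5siNS, and 0.56 with the block, lower in 3 of 3 left-out numbers each time. By the bound set beforehand, choosing genes on the siHic5siNS libraries does not explain all of it. The exact paired permutation p was 0.25 in each fit, the smallest that 3 pairs allow, so chance is not excluded. Genes that respond with and without Hic-5 kept 0.804 of their response (0.739 with the block). That share was above that of block genes in 3 of 3 numbers in both fits. Without the block 1 of the numbers held only 2 such genes. Their response was also lower than with siHic5siNS in 3 of 3 numbers in both fits. The mean log2 difference was -0.333 against -0.698 for block genes without the block, and -0.216 against -0.151 with it. Libraries labelled siCHD9siNS, without siHic5, gave similar shares of 0.52 for block genes and 0.805 for the others without the block. With the block these shares were 0.164 and 0.777, so for block genes the likeness was lost. The classes also differ by rule in the siNSsiNS call, so the shares do not decide about a weaker hormone response in general. The vehicle level moved on average by -0.248 of the lost response (-0.665 with the block), away from the direction of the dex response. Without the block the shifts by left-out number were -0.132, 0.069 and -0.457. This argues only against a starting level already shifted in the direction of the response. Responses were differences of log2(CPM + 0.5), on which a lower level can itself shrink the response of genes with low counts. That was not tested. For siBRMsiHic5 the same values were 0.589, 0.832 and 0.559 without the block, lower in 3 of 3 numbers, but with it the response was lower in only 2 of 3 numbers, the genes that respond with and without Hic-5 kept more of theirs in 2 of 3, and the vehicle level moved by 0.129 of the lost response, so the fits part and all 3 explanations stay open for siBRMsiHic5 (smallest exact paired permutation p = 0.25).

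Counts were also compared with those after exchanging group labels. With 10 splits per comparison there are too few for a share under 0.05, so only the values are given. For dex, 1 of 10 splits reached the real count of 52 with siNSsiNS (highest other 0), 2 of 10 reached 133 with siHic5siNS (highest other 169), 1 of 10 reached 148 with siCHD9siNS (highest other 0), 5 of 10 reached 58 with siBRMsiNS (highest other 2868), 1 of 10 reached 67 with siCHD9siHic5 (highest other 6) and 1 of 10 reached 76 with siBRMsiHic5 (highest other 15). Among the 4 splits that part all 3 pairs, the highest other count was 0 in each dex comparison. For vehicle, 1 of 10 splits reached 8066, 4898, 985, 7975 and 7430, with a highest other count of 0, 0, 883, 0 and 0 for siHic5siNS, siCHD9siNS, siBRMsiNS, siCHD9siHic5 and siBRMsiHic5. For the differences of responses, 1 of 10 splits reached the 1 gene for siCHD9siNS (highest other 0), and all 10 reached the count of 0 elsewhere. The 38 block genes were reached by 1 of 20 splits (highest other 5). With the block, the highest other count was 1, 0, 7 and 3 against 27, 626, 20 and 30 for the differences, and 306 against 456 for block genes.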

How the results depend on the processing

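Alternatives were planned before the data were examined, except the block within siRNA condition, TMM scaling, limma with a pseudocount of 0.5 (first planned as the test itself and made an alternative once the table was seen to hold counts) and the fit without the 6 siBRMsiNS libraries, which became alternatives, chosen after seeing the data. Of 531 values of comparisons under other settings, 422 stayed the same, 3 were stronger, 106 moved and 0 reversed; of 6345 values of named genes 6125 stayed and 220 were weaker, with 0 reversed. When libraries were left out, 300 of 423 values of comparisons stayed, 11 were weaker, 2 stronger and 110 moved, and 3503 of 4347 values of named genes stayed. For the values below the cause was not tested, unless named.

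With the replicate block within siRNA condition, the dex counts were 363 (siNSsiNS), 1329 (siHic5siNS), 3623 (siCHD9siNS), 588 (siBRMsiNS), 680 (siCHD9siHic5) and 905 (siBRMsiHic5), the differences 27 (siHic5siNS), 626 (siCHD9siNS), 20 (siCHD9siHic5) and 30 (siBRMsiHic5), the block genes 456, and their medians 0.0526 (siNSsiNS), 0.45 (siHic5siNS), 0.17 (siBRMsiNS), 0.16 (siCHD9siHic5) and 0.12 (siBRMsiHic5); the median dex response of block genes with siCHD9siNS was 0.0143, and 0 lists differed for siBRMsiNS. With the number as a block over all groups, dex with siCHD9siNS gave 234, its difference 0, vehicle siBRMsiNS 2232, block genes 62, the medians with siNSsiNS, siHic5siNS and siCHD9siNS 0.32, 1.31 and 0.30, and CHD9 with siCHD9siHic5 and dex a log2 change of 0.39 (adjusted p = 0.05). With only the compared groups in the fit, which leaves fewer samples, dex gave 35 (siHic5siNS), 65 (siCHD9siNS), 0 (siBRMsiNS), 19 (siCHD9siHic5) and 4 (siBRMsiHic5), the siCHD9siNS difference 0, vehicle siBRMsiNS 0, block genes 13, and the medians 1.09, 2.19, 1.04, 1.28, 1.39 and 1.59. DESeq2 gave 210 (siHic5siNS), 283 (siCHD9siNS) and 118 (siBRMsiHic5) for dex, differences of 23 (siCHD9siNS), 1 (siCHD9siHic5) and 1 (siBRMsiHic5), 1494 for siBRMsiNS against siNSsiNS with vehicle, and medians of 0.27 (siNSsiNS) and 0.33 (siBRMsiNS). Without the 6 siBRMsiNS libraries dex with siCHD9siNS gave 234, its difference 2, and the medians 0.33, 1.29 and 0.28.

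Quantile normalization gave differences of 2 (siHic5siNS), 0 (siCHD9siNS) and 2 (siCHD9siHic5), and medians of 0.27 (siNSsiNS), 1.19 (siHic5siNS), 0.24 (siCHD9siNS), 0.35 (siBRMsiNS) and 0.27 (siCHD9siHic5). In the same order limma with a pseudocount of 1 gave 2, 0 and 3, and 0.22, 1.00, 0.16, 0.32 and 0.23; limma without trend or robust steps gave 2 (siHic5siNS) and 2 (siCHD9siHic5), and 0.30, 1.16, 0.26, 0.39 and 0.25; limma with a pseudocount of 0.5 gave 0 (siCHD9siNS) and 1 (siCHD9siHic5), and 0.31, 1.19, 0.27 and, with siCHD9siHic5, 0.26; with a pseudocount of 0.1 the siCHD9siNS median was 0.29. A mean CPM of 1 or more, with fewer genes tested, gave 0 for the siCHD9siNS difference and medians of 0.35 (siNSsiNS) and 1.31 (siHic5siNS). A fold of 1.5 or more, a stricter call, gave 2910 for siCHD9siNS against siNSsiNS with vehicle, 611 for siBRMsiNS against siNSsiNS with vehicle, and a siCHD9siNS median of 0.38. Among siRNA targets: CHD9 with siCHD9siHic5, dex gave 0.46 with median-ratio scaling (adjusted p = 0.0322) and 0.46 with TMM (adjusted p = 0.0332), and its adjusted p ranged from 0.0322 to 0.312 over all alternatives. Block genes numbered 0 with an adjusted p for the difference and 94 with no condition on it. Held out, the medians were 0.79 (siNSsiNS), 1.24 (siHic5siNS), 0.65 (siCHD9siNS) and 0.54 (siCHD9siHic5). With an estimated correlation, lists called for dex went from 7, 5, 6, 5, 5 and 8 to 3, 3, 4, 3, 3 and 3, from 1 to 0 for the siBRMsiNS difference, and for vehicle from 5, 3, 4, 4 and 7 to 0, 0, 2, 0 and 1.

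Leaving out 1 library or 1 number, dex counts ranged over 5 to 41 (siNSsiNS), 17 to 113 (siHic5siNS), 2 to 107 (siCHD9siNS), 0 to 77 (siBRMsiNS), 13 to 56 (siCHD9siHic5) and 5 to 103 (siBRMsiHic5), the siCHD9siNS difference over 0 to 6, and vehicle counts over 5627 to 7552, 1397 to 4721, 6 to 2366, 5453 to 7507 and 4367 to 7091 (siHic5siNS, siCHD9siNS, siBRMsiNS, siCHD9siHic5, siBRMsiHic5). CHD9 ranged over -0.68 to -0.46 with siCHD9siNS and vehicle and 0.35 to 0.55 with siCHD9siHic5 and vehicle (0.25 to 0.52 with dex). Block genes ranged over 7 to 43, with medians of 0.29 to 1.47, 1.28 to 3.41, 0.27 to 1.32, 0.35 to 1.84, 0.33 to 1.06 and 0.48 to 1.22. How far depth limits the counts was not tested; at the depth and with the 3 replicates of these libraries, simulated changes of 1.5-fold were found in 26.9% of genes without the block.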

Other observations

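Of the osteoblast genes, RUNX2, the master factor of bone formation, fell by 1.73 on the log2 scale with siBRMsiHic5 against siNSsiNS with vehicle, while SPP1, osteopontin, rose by 3.03 ± 0.68. In the same way with siHic5siNS, BMP4 fell by 2.38 on the log2 scale and TNFRSF11B rose by 1.80 ± 0.35.

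The share of counts from RNA28S5 was 5.46% in vehicle replicate 3 of siNSsiNS and 0.722% in its dex partner, so pairs of libraries with the same number were not always alike in this share.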
